A study of Mus musculus with 6 samples.

How the data were processed

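RNA of mouse placentae was profiled in 6 droplet libraries from 2 genotypes, Qpct+/+ (wild type) and Qpct-/- (knockout). Qpct encodes glutaminyl-peptide cyclotransferase, an enzyme that turns an N-terminal glutamine of a peptide into pyroglutamate, and the series title describes it as imprinted. A pair of libraries, 1 per genotype, held single cells, and 4 libraries, 2 per genotype, held single nuclei. Per the labels' protocols, the cells were released with protease and sorted for live cells, and the nuclei were freed in a lysis buffer with a dounce homogeniser. The design text describes pools of 5 placentae and does not say whether the 2 nuclei libraries of a genotype came from separate pools, so that p-values measure the spread between these libraries, which may be technical. The strain, C57BL/6, is given for the single cells alone. The labels place all 6 libraries at embryonic day 15.5, whereas the deposited names of the 4 nuclei tables carry day 13.5. The labels were followed, and this conflict stays open for every nuclei value.

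Each deposited file was a table of whole-number UMI counts per gene and barcode, not normalised by the authors. Per the submitters' processing notes, the counts were made with Cell Ranger 5.0.1 for the cells and 6.1.2 for the nuclei on the mouse genome build mm10, which is the assembly GRCm38. Settings for cell calling, intronic reads and strand were not given in the sources used here. The tables listed 32285 genes, of which 32158 had a position in the annotation used (GRCm38). The lowest barcode total was 500 UMIs. The deleted part of Qpct was not given either, and the tag of a 3' assay can lie outside it, so that Qpct counts in the knockout libraries may check nothing.

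Barcodes were kept with at least 500 genes and under 5% mitochondrial counts for nuclei, and with at least 300 genes and under 20% for cells. Doublets were scored per library with Scrublet as implemented in scanpy 1.11.5. Its automatic threshold called 0 to 1 barcodes per nuclei library and 1 and 11 in the cells and had therefore not worked. In its place, after the scores were seen, the highest-scoring barcodes were removed at a rate of 0.8% per 1000 barcodes with a maximum of 8%, which took 2.65% to 7.86% of a library. Kept were 17639 and 11087 wild-type nuclei, 21339 and 25632 knockout nuclei, 6875 wild-type cells and 3602 knockout cells. Kept counts per nuclei library ranged from 53907278 to 91664798, and the cells gave 44284182 and 30535177. Intervals and floors of 3 counts given below cover counting error only.

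Nuclei and cells were clustered apart. Counts were scaled to 10000 per barcode and log-transformed, 3000 variable genes were scaled with a maximum of 10, and 50 principal components with 15 neighbours went into Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9). Clusters were named from fixed marker lists, where a marker counted as raised at 2-fold or more over the other barcodes with a UMI in at least 5% of the cluster. A name needed 3 raised markers and stands here as "X-like". The marker fold of 2 was chosen after a fold of 1.5 had been tried. A further exception was made after the data were seen. A single-cell cluster led by Mpo, Acta2, Col1a1 and Prtn3, with 39 wild-type and 225 knockout cells, had passed as mesenchyme and was left unnamed. Of the clusters, 4 of 27 in the nuclei and 7 of 35 in the cells stayed unnamed.

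Nuclei are not replicates, so counts were summed per library, or per library and class, and the 4 sums were tested. The test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling, the filterByExpr filter on low counts, genotype as the term and Benjamini-Hochberg adjustment at 0.05. A class entered with at least 100 nuclei in every library. TMM factors were 0.991, 0.993, 0.950 and 1.07. Chi-square tests of the counts of any 2 nuclei libraries gave 79.2 to 191 per degree of freedom, so that none repeated another. Gene lists were tested with camera in limma 3.58.1 at its preset correlation of 0.01, on voom values, with adjustment over the lists or over lists and classes. The difference between zones was the interaction of genotype and class, with library as a block, between the labyrinth and the junctional zone class with the most nuclei. Parietal giant cells were not counted as junctional zone in this choice, although they held 6103 nuclei against 4629 of the spongiotrophoblast class. Class shares were compared by a two-sided exact permutation test, where 2 libraries against 2 cannot give a p below 0.333. Single cells had 1 library per genotype and no test. Their values are counts per 1e6 counts (CPM) with exact Poisson intervals, ratios with exact conditional intervals and shares with Clopper-Pearson intervals, all at 95%. A list's median log2 ratio in single cells is given with its percentile among 10000 random lists matched on expression. Random lists do not keep the correlation among the genes of a list, and the percentile covers no spread between libraries.

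The marker lists, the gene lists, the test of each comparison and the rule for named genes were fixed before the data were examined. Qpct is named always. For whole nuclei libraries the rule takes, among genes past the threshold with every knockout library beyond every wild-type library and a mean of at least 10 CPM in 1 genotype, the 12 largest rises and 12 largest falls. For a class it takes the 4 largest each way at a mean of at least 20 CPM, and where none pass, the same number by p, as values without calls. Each list names up to 4 members with the smallest p, and the interaction 4 in each direction. In single cells the 5 largest ratios each way are named, in the whole library and the 4 classes with the most cells, among genes with at least 100 counts in 1 library, ranked by the interval bound nearest to 1. In single cells, haemoglobin, sex-linked and mitochondrial genes are named with their list only. Other genes named in the text were chosen after their values were seen, and their sentences say so.

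The fits were tested on simulated counts with 200 genes changed 2-fold or 4-fold before use, and outside the interaction with a list of 30 further genes changed 1.5-fold. In the whole-library comparison edgeR recovered 57% of genes changed 2-fold and 99% of those changed 4-fold, with 8 false calls among 171, where calls in the 1.5-fold list are not false. In the sinusoidal trophoblast giant cell class it recovered 81% and 100%, in the macrophage class 53% and 100%, and in the interaction 53% and 95%. Changed genes were drawn from those above a minimum mean count, so genes with low counts lie outside these rates. Each simulated gene varied independently, with a spread set by its level of expression.

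Alternatives fixed in advance were DESeq2 1.42.0, its size factors within edgeR, no filter on low counts, a replicate block, each library left out, doublets kept, at least 1000 genes per barcode, all deposited barcodes, Leiden resolution 2, centring of genes within libraries, edgeR on class counts, a trophoblast denominator, camera with an estimated correlation, fry, and TMM scaling of the single cells. Added after the data were seen were at least 1000 genes for the class tests, autosomal genes alone, nuclei of named classes as sums or denominator, TMM over class counts, parietal giant cells in place of spongiotrophoblast and the endoderm class without its Afp-led cluster. Also chosen then were the omission of a pruning step in the neighbour graph and the removal of a fit with crossed replicate numbers, which the check of those numbers did not call for. Further tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, statsmodels 0.14.6 and matplotlib 3.10.9.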

Results

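Mouse placentae with and without Qpct were compared as single cells, with 1 library per genotype, and as single nuclei, with 2 libraries per genotype. The series title concerns abnormal angiogenesis and placentation on loss of this imprinted gene. The single-cell libraries kept 6875 wild-type and 3602 knockout cells with 44284182 and 30535177 UMI counts. The nuclei libraries kept 17639 and 11087 wild-type nuclei with 72502797 and 53907278 counts, and 21339 and 25632 knockout nuclei with 77380704 and 91664798 counts. Median counts per barcode were 1813, 1975, 1746 and 1770 in the nuclei, in the order wild type replicates 1 and 2 and knockout replicates 1 and 2, and 3888 and 3752 in the cells. Groups of nuclei and cells are called by the markers they raised, as "X-like". The nuclei tables carry embryonic day 13.5 in their deposited names, 2 days earlier than in their labels, so the stage behind every nuclei value is uncertain.

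Qpct, the targeted gene (ENSMUSG00000024084, GRCm38 chromosome 17, 79051906 to 79090378, plus strand), was lower in the knockout single cells. It reached 15.8 CPM (95% Poisson interval 14.6 to 17, 698 counts) in the wild-type cells and 3.24 CPM (2.64 to 3.95, 99 counts) in the knockout cells. In decidual stroma-like cells, which are maternal, it stood at 127 and 110 CPM, and in macrophage-like cells at 18.6 and 5.76 CPM. In NK or T cell-like cells with Xist and no Y-linked UMI, Qpct was at 11.4 and 9.31 CPM. Decidual stroma-like cells numbered 114 in the wild type and 16 in the knockout, so the whole-library fall of Qpct mixes shares with levels. In nuclei it was near the detection limit: 94 counts in wild type replicate 1, 2 in wild type replicate 2, 11 in knockout replicate 1 and 8 in knockout replicate 2. These are 1.30 CPM (1.05 to 1.59), 0.0371 (0.00449 to 0.134), 0.142 (0.0710 to 0.254) and 0.0873 (0.0377 to 0.172). The log2 fold change (log2FC), knockout over wild type, was -2.61 (SE 1.14, edgeR adjusted p = 1.00). Without wild type replicate 1 the sign turned, to 1.56, and without the filter on low counts the change of -2.60 passed the threshold. Wild type replicate 2, at 2 counts, therefore lies with the knockout libraries, whose intervals overlap its own, and goes against its label. It is written below as the library labelled wild type replicate 2, and every genotype direction in the nuclei draws on it. The deleted part of the gene is not given and these are 3' tags, so Qpct counts may check no label at all. Qpctl, which encodes the related Golgi enzyme, was at 14, 14.5, 15.0 and 13.1 CPM in the 4 nuclei libraries.

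Sex-linked genes separated the genotypes in every nuclei library. Uty, on the Y chromosome, was at 77.2 CPM in wild type replicate 1 and 82.8 CPM in the library labelled wild type replicate 2, against 0.0775 and 0.164 CPM in the knockouts. Xist, the RNA that silences an X chromosome, was at 55.5 and 58.8 CPM against 738 and 1051 CPM. In decidual stroma-like nuclei Xist was high in all 4 libraries (738, 774, 693 and 1054 CPM), and in sinusoidal trophoblast giant cell-like nuclei it was at 2.87 and 3.01 against 602 and 908 CPM. The single cells gave 682 counts of Ddx3y (15.4 CPM) in the wild type and 0 in the knockout (95% upper bound 0.121 CPM), while Xist was at 704 and 868 CPM. The mitochondrial share also moved with genotype in the nuclei, at medians of 1.76% and 1.37% in the wild types and 0.939% and 0.904% in the knockouts. In the cells both medians were 3.0%. The nuclei libraries cannot separate genotype from this split of sex-linked genes, and it stands beside every gene group below.

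**Figure D1:**
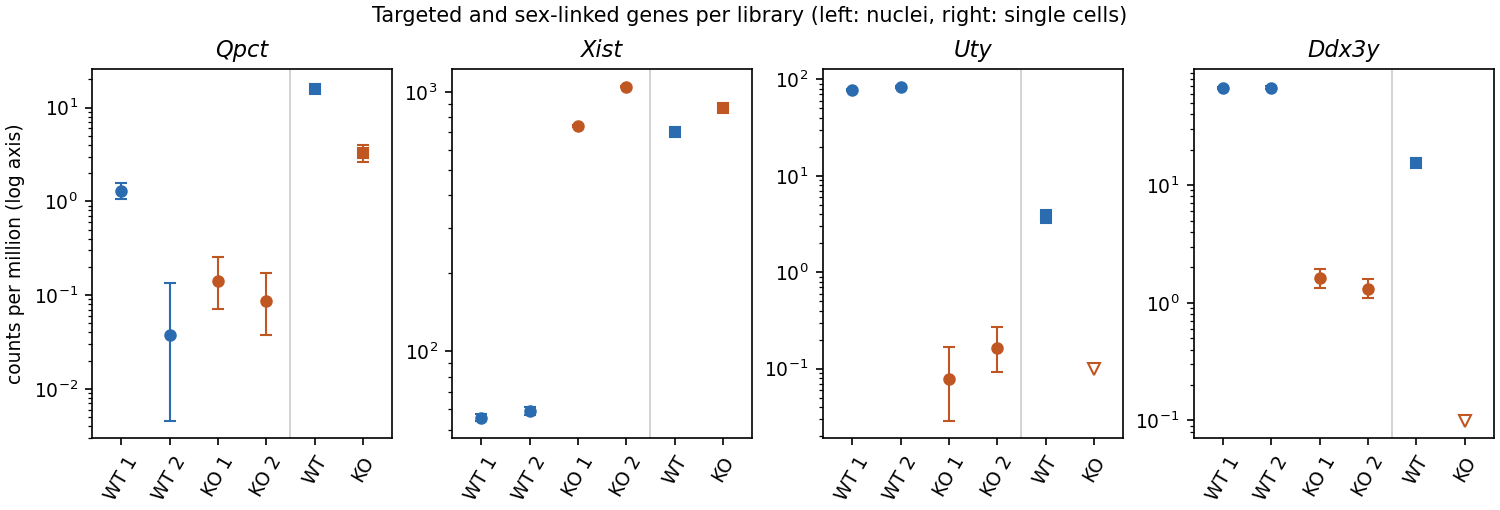
CPM (log axis) of the targeted gene and of sex-linked genes in each of the 4 nuclei and 2 single-cell libraries, with 95% Poisson intervals as bars. Uty lies at 77.2 and 82.8 CPM in the wild-type nuclei libraries and at 0.0775 and 0.164 CPM in the knockouts. Qpct in the library labelled wild type replicate 2 (0.0371 CPM) lies near both knockouts, with an interval that overlaps theirs.

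Across the whole nuclei libraries, the question was which transcripts differ with genotype. Adamts13, the protease that cleaves von Willebrand factor, fell from 10.5 ± 0.85 to 0.668 ± 0.012 CPM (mean ± SD, n = 2 and 2). This is a log2FC of -4.00 (SE 0.23, edgeR adjusted p = 0.00117), a fitted level 15.9 times lower. Apob, the main protein of large lipoproteins, went from 70.7 ± 15.7 to 5.53 ± 3.12 CPM (adjusted p = 0.0489), and the apolipoprotein gene Apoa2 from 17.7 and 28.9 CPM to 1.96 and 0.840 CPM (adjusted p = 0.0484). Ttr, a carrier of thyroid hormone, went from 26.4 and 39.2 CPM to 5.16 and 4.19 CPM (adjusted p = 0.0125).

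Of 20285 genes tested, 2 rose and 17 fell. The rises were Xist (3.93, SE 0.23) and Tsix (2.78), whose reads overlap on opposite strands, so that Tsix is uncertain. The falls held 6 Y-chromosome genes, among them Uty (-9.35), Eif2s3y (-8.65), Kdm5d (-7.54) and Ddx3y (-5.53). The other 11 were autosomal, and besides those above they were Serpina1a (-4.78), Fgg (-3.91), Fgb (-3.76), Agt (-3.60), Alb (-3.22), Apoc2 (-2.95) and Apom (-2.22), which were named after their values were seen. Of the autosomal genes 0 rose in edgeR. With the replicate number as a block, 4 of the 19 calls and 0 of the 11 autosomal ones were kept. Summing nuclei of named classes alone kept 14 and 7. At an unadjusted p under 0.05 there were 632 genes, and DESeq2 called 54, with 19 higher and 35 lower. The count was 16 without wild type replicate 1, 5 without the library labelled wild type replicate 2, 124 without knockout replicate 1 and 175 without knockout replicate 2. Without the library labelled wild type replicate 2, only Adamts13, Uty, Eif2s3y, Kdm5d and Ddx3y of the 19 genes kept their calls, so that 1 of the 11 autosomal calls was kept, and Apob and Apoa2 also lost them with DESeq2's size factors.

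Among the gene lists, those of angiogenesis, the process named in the title, did not pass the threshold in the whole nuclei libraries. With 2 libraries against 2, this does not show that the genotypes are equal. Angiogenic signalling had 24 of 41 measured members higher, a median log2FC of 0.04 and a camera adjusted p of 0.60. Its members with the smallest p were Apln (0.62), Angpt1 (0.72), Dll4 (-0.42) and Plxnd1 (-0.24), and none passed. Endothelial identity had 13 of 21 higher and a median of 0.06 (adjusted p = 0.472), with Cldn5 at 0.28, Fli1 at 0.28, Kdr at 0.21 and Ptprb at 0.22. The 22 genes beside Qpct on chromosome 17, within 1.58 Mb, had a median of 0.01 (adjusted p = 0.60).

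In the whole nuclei libraries 8 of 26 lists passed camera at its preset correlation. None passed with an estimated correlation, where every list outside the sex-linked ones had an adjusted p of 0.937. Interferon response genes rose as a list, with 24 of 27 higher and a median of 0.29 (adjusted p = 4.55e-10, lost without knockout replicate 1). Their leading members were the antiviral genes Ifi44 (0.68), Rsad2 (0.50), Gbp7 (0.48) and Trim30a (0.41), none of which passed alone. Nuclear-encoded oxidative phosphorylation rose with 27 of 30 higher and a median of 0.13 (adjusted p = 1.89e-04). It lost the call without knockout replicate 1 and turned downward without the library labelled wild type replicate 2. Genes for pyroglutamate peptides and their receptors rose with 11 of 14 higher (median 0.14, adjusted p = 0.0321), led by Apln (0.62) and Sirpa (0.38), the receptor of Cd47. That list passed neither without wild type replicate 1, nor without the library labelled wild type replicate 2, nor without knockout replicate 1. Prolactin family genes, hormones of giant cells and spongiotrophoblast, fell with 17 of 25 lower (median -0.10, camera adjusted p = 0.00571), led by Prl7a1 (-0.72), Prl2c3 (-0.75) and Prl2c2 (-0.53). These members also lead the parietal giant cell-like class, which made up 10.5% and 14.8% of wild-type and 6.86% and 4.49% of knockout nuclei. The prolactin fall therefore mixes shares with levels. Endoplasmic reticulum stress genes fell with 13 of 20 lower (median -0.14, adjusted p = 0.0175), led by Sesn2 (-0.47) and Atf4 (-0.35). Without knockout replicate 2 both of these lists turned upward, and without wild type replicate 1 both lost their calls. All 13 mitochondrially encoded genes were lower (median -0.75, adjusted p = 2.22e-15), with mt-Nd1 at -0.81, in the libraries with the lower mitochondrial share. The 4 Y-linked genes fell (median -8.10, adjusted p = 1.93e-30, 0.181 with an estimated correlation), and the 2 X inactivation transcripts rose (median 3.36, adjusted p = 1.83e-14, 0.379 with an estimated correlation). Adjusted over the list alone, those 6 genes passed, as did 1 fall in haemoglobin and red cell genes, Hbb-y (-1.98), the embryonic beta-globin.

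The remaining lists did not pass in the whole nuclei libraries. Maternally expressed imprinted genes had 20 of 33 higher (median 0.07, mean -0.00, camera downward, adjusted p = 0.758), with Slc22a2 at -1.43. Paternally expressed imprinted genes had 12 of 30 higher (median -0.03, adjusted p = 0.472), with Nap1l5 at 1.80 and the amino acid transporter Slc38a4 at -0.65. Psg and Ceacam genes had 14 of 21 higher (median 0.05, camera downward, adjusted p = 0.758), and placental cathepsins 8 of 11 (median 0.21, adjusted p = 0.222). Nutrient transport had 14 of 36 higher (median -0.06, adjusted p = 0.450), with the endocytic receptor Lrp2 at -0.78 and the calcium-binding S100g at 0.88. Hypoxia response had 8 of 21 higher (median -0.06, adjusted p = 0.25), extracellular matrix 22 of 37 (0.06, 0.544) and inflammatory cytokines 8 of 18 (median -0.02, mean 0.02, camera downward, 0.890). Immediate early and heat shock genes had 11 of 22 higher (median 0.01, mean -0.05, camera downward, 0.607), S phase 14 of 29 (-0.02, 0.868) and G2 and M phase 23 of 32 (0.07, 0.60). Glycogen metabolism had 8 of 19 higher (-0.01, 0.558) and cholesterol and steroid synthesis 5 of 23 (-0.13, 0.0879), although the steroid enzyme Cyp17a1 in it was at 0.77. Haemoglobin and red cell genes had 11 of 14 higher (median 0.10, mean -0.12, camera upward, 0.758), and decidual and uterine genes 11 of 14 (0.19, 0.60).

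Within classes, the comparison asks which cell types carry a difference once shifts in the shares of the classes are removed. Shifts among the clusters inside a class are not removed. The same few genes fell nearly everywhere. Among 12 classes, Ddx3y and Uty fell in 12, the fetal plasma protein Afp in 11 (log2FC -4.31 to -2.82), Apob in 10 (-5.09 to -3.02) and Apoa1 in 9. In wild-type decidual stroma-like nuclei, which are maternal, Afp still stood at 128.5 and 118.3 CPM. A fall called in a class may therefore come from free RNA, which is taken up below. Adamts13 fell in 5 of the 10 classes where it was tested: parietal giant cell-like (-5.38), spongiotrophoblast-like (-5.11), sinusoidal giant cell-like (-4.48), syncytiotrophoblast I-like (-4.27) and erythroid-like nuclei (-3.72). The 209 calls concerned 105 genes. Of these, 14 genes with 69 calls lay on the X or Y chromosome, 15 genes were called in 3 classes or more and 85 in 1 class.

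Sinusoidal trophoblast giant cell-like nuclei, which in mouse line the maternal blood spaces of the labyrinth, held most of the autosomal rises, with 25 genes up and 27 down of 14698. It was also the named class with the most nuclei (10929), with 10305608 to 22343673 counts per library. Counts of calls between classes of unlike depth therefore do not rank their responses. Cyp17a1, an enzyme of androgen synthesis, rose from 14.7 and 20.3 CPM to 49.1 and 41.6 CPM (log2FC 1.38, SE 0.18, edgeR adjusted p = 0.00286). The potassium channel gene Kcnh1 rose from 63.3 and 49.5 CPM to 145 and 404 CPM (2.28, SE 0.32, edgeR adjusted p = 0.00701) and lost the call with DESeq2 and with doublets kept. Its log2FC was 1.40 without knockout replicate 2 and 2.80 without knockout replicate 1. Of the genes that fell by the rule, Apoa1 went from 27.4 and 19.9 to 2.70 and 1.43 CPM (-3.59), beside Uty, Eif2s3y and Ddx3y. Chosen after their values were seen, further rises were the guidance receptor Unc5c (2.15), the growth factor Pdgfd (1.42), Tbx20 (1.36), Ccn2 (1.09), Ptprb (0.99), the lymphangiogenic Ccbe1 (0.87) and the protease inhibitor Timp3 (0.78). Further falls, chosen likewise, were the kinase Hunk (-1.18; 115 and 87.2 against 38.2 and 50.5 CPM), Srd5a1 (-0.97), which acts downstream in androgen metabolism, the semaphorin receptor Plxnd1 (-0.78), the amino acid transporter Slc7a5 (-0.73), Sema4g (-0.71) and Ntn1 (-0.68). X-linked rises held S100g (1.34) and Ogt (0.77). At an unadjusted p under 0.05 there were 1590 genes, and DESeq2 called 114. The count was 215 without wild type replicate 1, 407 without the library labelled wild type replicate 2, 97 without knockout replicate 1 and 150 without knockout replicate 2. It fell to 27 with doublets kept and to 27 with at least 1000 genes per nucleus. Of the 40 autosomal calls, 17 passed again with doublets kept and 19 with at least 1000 genes per nucleus. Ptprb also belongs to the endothelial identity list. Whether free RNA of other cells carries rises in this class was not tested.

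**Figure D2:**
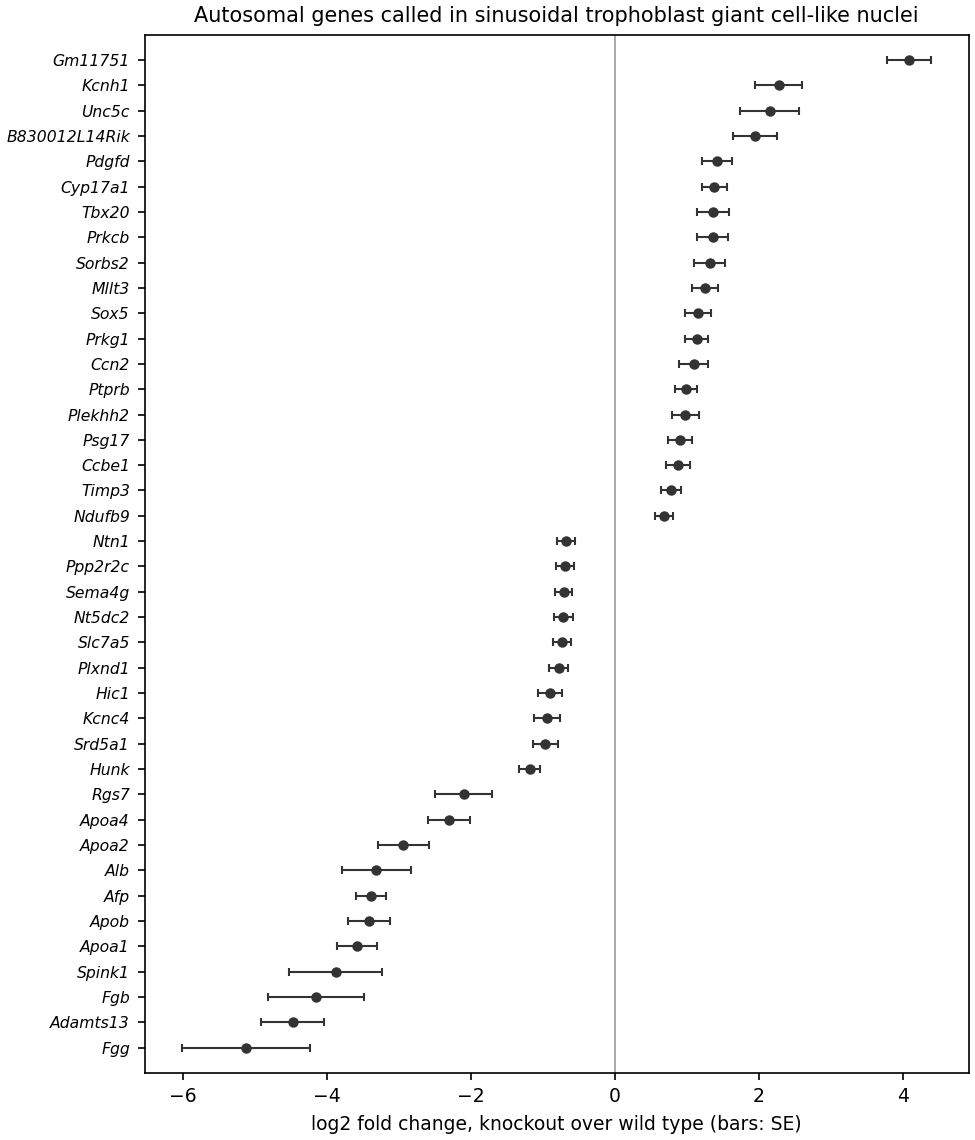
Log2 fold change, knockout over wild type, of each autosomal gene called in sinusoidal trophoblast giant cell-like nuclei (edgeR, n = 2 and 2 libraries; bars, SE), with 1 gene per line of the vertical axis. Of 40 genes, 19 lie above 0, up to Gm11751 at 4.09, and 21 below.

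Endoderm-like nuclei, of visceral or parietal endoderm, had 7 genes up and 59 down of 11613 (DESeq2 75 calls). By the rule, Gm12648 (3.96, SE 0.62, edgeR adjusted p = 0.0268) and Suv39h2, a histone methyltransferase (2.67), rose beside Xist (6.98) and Tsix (2.60). With 1 library left out, Gm12648 ranged from 2.91 to 6.64 and Suv39h2 from 1.785 to 3.45. Meltf, encoding melanotransferrin, was at 11 and 29.2 CPM in the wild types and at 0 counts in both knockouts, at least 36.4-fold lower over the group. Eif2s3y (-8.45), Uty (-8.30) and Kdm5d (-7.19) fell too. Chosen after their values were seen, Alb (-4.12), Agt (-4.82), Serpina1a (-5.87) and Apoc2 (-5.25) fell, as did the endocytic receptors Lrp2 (-1.35) and Cubn (-1.98), and Ccn2 rose (2.10). The class holds a cluster led by Afp. Without that cluster, 8 genes were called, and of the 66 genes called before, 37 could be tested, 8 passed again and 2 turned their sign. Gm12648 and Suv39h2 lost their calls with DESeq2 and without that cluster. So did Gm12648 without wild type replicate 1, and Suv39h2 and Meltf without the library labelled wild type replicate 2. The count was 71 without wild type replicate 1, 28 without the library labelled wild type replicate 2, 129 without knockout replicate 1 and 177 without knockout replicate 2.

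Fetal endothelium-like nuclei, the class closest to the angiogenesis of the title, had 3 genes up and 7 down of 12285 (649 at an unadjusted p under 0.05, DESeq2 22). Aff3, a nuclear protein gene of transcription elongation, rose from 54.1 and 53.9 CPM to 104 and 112 CPM (log2FC 0.99, SE 0.12, edgeR adjusted p = 0.0323). It lost the call with doublets kept and at a finer clustering. Xist (3.65) and Tsix (2.95) rose. In the wild types Xist was at 50.5 and 91.4 CPM, against 4.14 and 1.69 CPM in mesenchyme-like nuclei. The endothelium-like class may therefore also hold maternal nuclei. Uty and Eif2s3y had no knockout counts, at least 731-fold and 405-fold lower, Kdm5d was at least 182-fold lower and Ddx3y fell (-7.00). Angiogenic genes gave no call there. Chosen for that reason, Kdr was at 398 and 411 against 393 and 387 CPM (-0.06), Flt1 at -0.13, Pecam1 at -0.03, Cdh5 at -0.04, Tek at -0.05, Vegfa at -0.00 and Dll4 at -0.41 (edgeR adjusted p = 0.821). The count of calls was 26 without wild type replicate 1, 16 without the library labelled wild type replicate 2, 17 without knockout replicate 1 and 129 without knockout replicate 2.

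Parietal trophoblast giant cell-like nuclei, at the border to the decidua, had 2 genes up and 10 down of 11130 (807 at an unadjusted p under 0.05, DESeq2 27). Adamts13 fell from 20.6 and 20.4 CPM to 0.547 and 0.416 CPM (log2FC -5.38, SE 0.42, edgeR adjusted p = 7.86e-04), with Apob (-3.90), Apoa1 (-3.87) and Ddx3y (-4.24), while Xist (5.01) and Tsix (4.06) rose. Jak3, a cytokine receptor kinase named after its value was seen, fell as well (-1.5, adjusted p = 0.0252). Spongiotrophoblast-like nuclei had 2 up and 5 down of 13439, which held Xist (9.59), Tsix (7.04), Uty (-9.86), Ddx3y (-5.98), Adamts13 (-5.11) and Afp (-3.65). Glycogen trophoblast-like nuclei had 2 up and 4 down of 12929, where the autosomal call was Apoa1 (-3.09), beside Xist (7.12), Tsix (4.83), Uty (at least 763-fold lower), Kdm5d (at least 104-fold lower) and Ddx3y (-6.47). In these 3 classes, in the order wild type replicate 1, the library labelled wild type replicate 2, knockout replicate 1 and knockout replicate 2, leaving out a library gave 31, 67, 83 and 34, then 12, 132, 24 and 24, then 6, 3, 59 and 25 calls. The glycogen class lost Apoa1 without either wild-type library and Tsix and Kdm5d without the library labelled wild type replicate 2, and the spongiotrophoblast class lost Afp with doublets kept. DESeq2 called 18 and 11 genes in the latter 2 classes, and 390 and 318 lay at an unadjusted p under 0.05.

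Syncytiotrophoblast I-like nuclei, the layer that meets maternal blood, had 1 gene up, Xist (7.35), and 9 down of 13824, with Uty at least 576-fold lower, Eif2s3y at least 472-fold lower, Kdm5d at -7.32 and Ddx3y at -6.08. Syncytiotrophoblast II-like nuclei, the layer toward fetal vessels, had 3 up and 12 down of 12920. By the rule these were Xist (7.44), Tsix (2.45), Uty (at least 162-fold lower), Eif2s3y (at least 94.0-fold lower), Ddx3y (-6.21) and Apob (-4.04, edgeR adjusted p = 3.29e-06), and Gm11751 (4.23), the third rise, was named after its value was seen. Fetal mesenchyme and pericyte-like nuclei had 2 up and 6 down of 12245, led by Xist (8.33) and Tsix (6.11), with Uty at least 358-fold, Eif2s3y at least 299-fold and Kdm5d at least 156-fold lower and Ddx3y at -7.84. Erythroid-like nuclei had 2 up and 11 down of 13004, with Xist (5.35), Tsix (2.43), Eif2s3y (-7.51), Uty (-6.50), Ddx3y (-5.21) and Apob (-3.39). In that order of classes, the 4 libraries left out as above (wild type replicate 1, the library labelled wild type replicate 2, knockout replicate 1, knockout replicate 2) gave 23, 53, 23 and 39, then 18, 35, 17 and 46, then 8, 11, 55 and 56, then 10, 13, 17 and 23 calls. Tsix lost its call with DESeq2 in syncytiotrophoblast II-like nuclei and without wild type replicate 1 in erythroid-like nuclei.

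Decidual stroma-like and macrophage-like nuclei had the fewest calls. The macrophage-like class was also the smallest one tested, with 963 nuclei and 599934 to 1341758 counts per library. Decidual stroma-like nuclei had 0 genes up and 5 down of 12256 in edgeR (373 at an unadjusted p under 0.05, DESeq2 7), among them Apob (-3.02), Apoa1 (-2.91) and Afp (-2.82). Among values above 0, given without a call, the smallest p belonged to Kcnmb2, a potassium channel subunit (3.17; 1.21 and 3.23 against 16.8 and 23.3 CPM, edgeR adjusted p = 0.0537), followed by S100g (1.11), Kcnh1 (2.16) and Gm9112 (1.09). Kcnmb2 passed with DESeq2, with its size factors, without the filter on low counts, with doublets kept and with any of the 4 libraries left out. Macrophage-like nuclei had 0 up and 5 down of 9661 in edgeR (394 at an unadjusted p under 0.05, DESeq2 12), with Apob (-5.09), Ddx3y (-5.71), and Uty and Eif2s3y at least 67.3-fold and 20.7-fold lower. Values without a call were Diaph3 (2.00), Xist (1.27), Hsd17b2 (1.16) and Ptprg (1.16). Without wild type replicate 1, the library labelled wild type replicate 2, knockout replicate 1 and knockout replicate 2, decidual calls numbered 27, 27, 27 and 18 and macrophage calls 3, 63, 1 and 0. In macrophage-like nuclei Ddx3y and Eif2s3y then lost their calls without wild type replicate 1 or either knockout library, Apob without either knockout library and Uty without knockout replicate 2.

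Of the gene lists within classes, 108 of 312 tests passed camera at its preset correlation, 67 upward and 41 downward. None passed with an estimated correlation and 1 passed fry, for mitochondrially encoded genes. Interferon response rose in 8 classes, with medians from 0.22 in syncytiotrophoblast I-like to 0.52 in spongiotrophoblast-like nuclei (smallest adjusted p with an estimated correlation 0.906). The count was 6, 9, 2 and 12 without wild type replicate 1, the library labelled wild type replicate 2, knockout replicate 1 and knockout replicate 2, the order of the 4 counts given below for other lists. Endothelial identity fell in endothelium-like nuclei themselves, with 3 of 21 genes higher and a median of -0.15 (adjusted p = 0.728 with an estimated correlation), and in mesenchyme-like nuclei (-0.42, 0.563). It rose in 5 trophoblast classes, up to 0.42 in sinusoidal giant cell-like nuclei (0.835; classes called with a library left out 7, 4, 7 and 2). Angiogenic signalling rose in parietal giant cell-like (0.20) and spongiotrophoblast-like nuclei (0.17), both at 0.906 with an estimated correlation (5, 0, 4 and 2). Psg and Ceacam genes, made by trophoblast, rose in 10 classes, the decidual one included (0.71), and fell in spongiotrophoblast-like nuclei, their main source (-0.31; smallest adjusted p with an estimated correlation 0.835; 11, 9, 6 and 11). Placental cathepsins rose in 10 classes (0.441 with an estimated correlation; 11, 6, 4 and 11). Droplets of nuclei also carry free RNA, and Hbb-bs, an adult beta-globin transcript of red cells, was at 399 to 10299 CPM in the other named classes against 15198 to 27350 CPM in erythroid-like nuclei.

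Mitochondrially encoded genes fell in 12 classes, from -1.32 in spongiotrophoblast-like to -0.54 in endothelium-like nuclei (0.441 with an estimated correlation). Oxidative phosphorylation rose in 6 classes (up to 0.27 in sinusoidal giant cell-like nuclei; smallest 0.906; 11, 8, 3 and 6 without wild type replicate 1, the library labelled wild type replicate 2, knockout replicate 1 and knockout replicate 2). Y-linked genes fell in 12 classes and X inactivation transcripts rose in 11 (smallest 0.441 for both). In sinusoidal giant cell-like nuclei the lists of maternally expressed imprinted genes (0.23, 0.728 with an estimated correlation), pyroglutamate peptides (0.21, 0.880), extracellular matrix (0.44, 0.835), haemoglobin (0.46, 0.906) and decidual genes (0.59, 0.906) rose too. Matrix genes rose in 3 classes and fell in 2, nutrient transport rose in 3 and fell in 1, haemoglobin rose in 2 and fell in 1, G2 and M phase rose in 2 and fell in 1, and prolactins rose in 2 and fell in spongiotrophoblast-like nuclei (-0.34). Decidual stroma-like nuclei had falls of hypoxia (-0.17), inflammatory (-0.49), cholesterol (-0.35) and decidual genes (-0.39). Endoplasmic reticulum stress fell in 2 classes, S phase in 1 and immediate early genes in 1. These class counts moved with the library left out. In the order above, classes called in either direction were 5, 4, 5 and 9 for matrix, 7, 4, 3 and 2 for nutrient transport, 10, 11, 6 and 2 for haemoglobin, 1, 6, 3 and 2 for G2 and M phase, and 6, 3, 8 and 10 for prolactins. They were 4, 0, 3 and 2 for hypoxia, 0, 1, 0 and 0 for inflammatory, 2, 4, 2 and 0 for cholesterol, 4, 2, 8 and 9 for decidual, 4, 2, 7 and 5 for stress, 3, 3, 5 and 2 for immediate early, 3, 2, 2 and 4 for maternally expressed imprinted genes and 0, 1, 0 and 1 for pyroglutamate peptides, while S phase stayed at 1. Each of these lists lost every class with an estimated correlation, and their smallest adjusted p values there were 0.835 for matrix, 0.906 for nutrient transport, 0.518 for haemoglobin, 0.883 for G2 and M phase, 0.906 for prolactins, 0.883 for hypoxia, 0.835 for inflammatory, 0.906 for cholesterol and for decidual genes, 0.906 for stress, 0.835 for S phase and 0.916 for immediate early genes. Paternally expressed imprinted genes, glycogen metabolism and the neighbours of Qpct passed camera in 0 classes, with fry also at 0. With a library left out, in that order, the paternally expressed genes passed in 1, 3, 1 and 6 classes, glycogen metabolism in 1, 0, 0 and 1, and the neighbours in 0 each time.

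Between zones of the placenta, the interaction asked whether the knockout effect differed between sinusoidal giant cell-like nuclei of the labyrinth and spongiotrophoblast-like nuclei of the junctional zone. No gene passed among 15098 in edgeR, with 682 at an unadjusted p under 0.05 and 1 call with DESeq2's size factors. The smallest p belonged to Erbb4, a receptor of the epidermal growth factor family, at log2FC -0.13 in the labyrinth and 3.73 in the junctional class (difference -3.90, SE 0.44, edgeR adjusted p = 0.150). Tsix (-2.36), Ripor2 (-1.58) and Dock6 (-1.14) followed in that direction. Frmpd4 (2.54), Psg17 (1.05), Cyp17a1 (1.03) and Fkbp11 (1.02) lay in the other, at an adjusted p of 0.941. The calls numbered 226 without wild type replicate 1, 1186 without the library labelled wild type replicate 2, 0 without knockout replicate 1 and 5 without knockout replicate 2.

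Class shares asked whether cell types were gained or lost. Parietal giant cell-like nuclei made up 12.6% ± 3.0 of wild-type and 5.67% ± 1.67 of knockout nuclei (SD, n = 2 and 2). Spongiotrophoblast-like nuclei were at 8.52% ± 1.24 and 4.82% ± 0.91, and syncytiotrophoblast II-like nuclei at 6.01% ± 1.25 and 4.70% ± 0.17. In these 3 of 13 classes both knockouts lay below both wild types, the library labelled wild type replicate 2 included, where chance separates 33.3% of classes. Each had p = 0.33 by the exact two-sided permutation test, the smallest that 2 against 2 can give (adjusted p = 1.00), and edgeR on the class counts gave the parietal class p = 0.0186 (adjusted p = 0.242). With doublets kept, the spongiotrophoblast difference turned to 9.26 points higher in the knockout.

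The other classes overlapped between genotypes, each with an adjusted p of 1.00 in the same exact permutation test. Shares in wild type and knockout were 12.3% ± 3.2 and 15.6% ± 7.1 for sinusoidal giant cell-like, 7.07% ± 0.71 and 6.79% ± 2.25 for syncytiotrophoblast I-like, 5.16% ± 0.30 and 5.38% ± 1.39 for glycogen trophoblast-like, and 4.45% ± 0.12 and 4.63% ± 2.36 for endothelium-like nuclei. They were 5.08% ± 0.61 and 6.32% ± 4.91 for decidual stroma-like, 5.40% ± 2.07 and 6.48% ± 1.88 for erythroid-like, 2.87% ± 0.08 and 3.16% ± 0.61 for endoderm-like, and 2.51% ± 0.05 and 2.60% ± 1.5 for mesenchyme-like nuclei. Macrophage-like nuclei were at 1.17% ± 0.13 and 1.33% ± 0.31 and B cell-like nuclei at 0.282% ± 0.086 and 0.266% ± 0.071. Unnamed clusters held 26.5% ± 3.9 and 32.3% ± 7.4, and 1 of them, led by Prl5a1, Prl8a2 and Doxl1, held 24.1% of knockout replicate 1 but 1.72%, 2.30% and 1.52% of the other libraries.

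**Figure D3:**
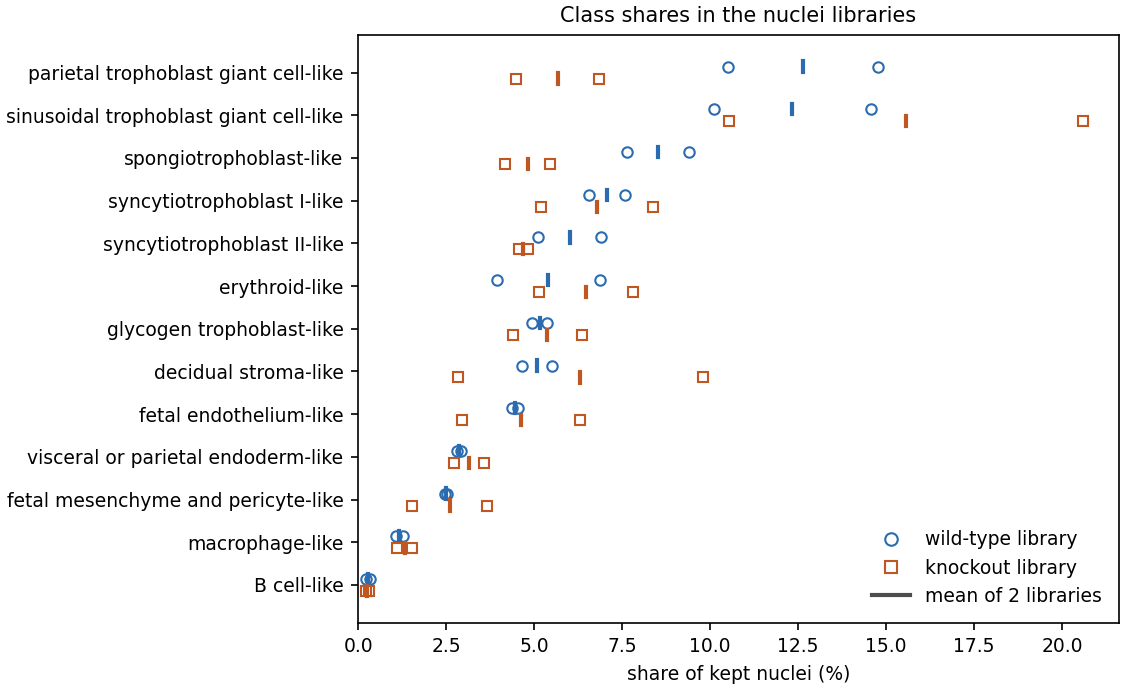
Share of kept nuclei (%) in each named class, per library (open points) with the mean of the 2 libraries per genotype (short lines). Parietal trophoblast giant cell-like nuclei lie at 10.5% and 14.8% in the wild types and 6.86% and 4.49% in the knockouts.

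In the single cells, 1 library per genotype allows no test, and a difference compares these libraries. Immune cells made up much of both, after a sort for live cells that can itself set the shares. Neutrophil-like cells held 11% (Clopper-Pearson interval 10.3 to 11.8) of wild-type and 20.6% (19.3 to 22.0) of knockout cells, and NK or T cell-like cells 7.54% and 11.9%. B cell-like cells were at 17% and 15.4%, macrophage-like cells at 16.9% and 16.8%, and endothelium-like cells at 4.00% and 2.83%. Several trophoblast classes and endoderm were lower in the knockout library: syncytiotrophoblast I-like cells went from 267 to 0 and sinusoidal giant cell-like cells from 55 to 0 (95% upper bound of each 0, 0.102%), glycogen trophoblast-like from 172 to 2, spongiotrophoblast-like from 86 to 1 and endoderm-like from 551 to 41. Erythroid-like cells went from 32 to 1 and decidual stroma-like cells from 114 to 16. In the other direction, parietal giant cell-like cells went from 43 to 91 (ratio 4.04), mast cell or basophil-like from 58 to 87 and megakaryocyte or platelet-like from 11 to 27. Unnamed clusters held 23.4% and 25.2%. The neutrophil ratio of 1.87 was 1.20 with at least 1000 genes per cell and 1.39 at a finer clustering. There the parietal ratio turned to 0.251 (38 and 5 cells), as a cluster of 5 wild-type and 86 knockout cells led by Ldoc1, Phlda2 and Hand1 was named junctional zone progenitor.

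Genes were also compared over the whole single-cell libraries, where shares and levels within classes mix. Psg16, Ceacam12 and Prl8a6, trophoblast genes, had 8330, 9240 and 5455 counts in the wild type and 1, 3 and 1 in the knockout. Prap1 and Guca2b, typical of epithelium, had 29511 and 9664 against 12 and 3. The granule enzyme gene Mpo was 305 times higher in the knockout (interval 193 to 515), Phlda2, an imprinted growth regulator, 174 times, Ldoc1 94.6 times, Gm15915 225 times (76.4 to 1094; 3 and 465 counts) and the carbonic anhydrase gene Car1 at least 148-fold. Whole-library medians of log2 ratios lay below all random lists for Psg and Ceacam (-7.99), cathepsins (-5.05), haemoglobin (-3.91), prolactins (-3.08), decidual genes (-1.27) and nutrient transport (-0.39). They lay above all for S phase (2.00), G2 and M phase (1.81), endothelial identity (0.85), cholesterol (0.75) and interferon response (0.64), and at percentile 99.2 for angiogenic signalling (0.39) and 98.2 for oxidative phosphorylation (0.33). The remaining medians and percentiles were -0.31 and 0.20 for immediate early, -0.13 and 4.13 for stress, -0.01 and 11 for hypoxia, -0.06 and 11.8 for paternally and 0.13 and 51.8 for maternally expressed imprinted genes. They were 0.04 and 33.0 for pyroglutamate peptides, 0.16 and 63.0 for inflammatory, 0.24 and 70.4 for glycogen, 0.06 and 71.3 for mitochondrial, 0.25 and 77.2 for neighbours of Qpct and 0.21 and 81.9 for matrix genes.

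Interferon response genes were higher in each of the 4 most abundant immune classes of the knockout library. The list's median log2 ratio was 1.43 in neutrophil-like (25 of 25 genes higher), 1.07 in macrophage-like (26 of 27), 0.95 in B cell-like (10 of 11) and 0.74 in NK or T cell-like cells (16 of 17), above all 10000 random lists in each. Genes that vary together can exceed random lists easily, so these percentiles are not tests of genotype. Isg15, a ubiquitin-like antiviral protein gene, was 10.7 times higher in neutrophil-like (9.73 to 11.8) and 7.55 times in macrophage-like cells (7.07 to 8.06). Ifit1bl1 was 6.99 times higher in macrophage-like cells, and the sensor gene Eif2ak2 and the signal transducer gene Stat1 were 3.18 and 2.94 times higher in B cell-like cells. In endothelium-like cells the median was -0.33 (5 of 15 higher, percentile 3.94). Wild-type cells with Xist only and with Y-linked UMIs only numbered 913 and 3 in B cell-like and 432 and 5 in NK or T cell-like cells. They numbered 921 and 89 in macrophage-like, 215 and 38 in neutrophil-like, and 82 and 63 in endothelium-like cells. Many of the immune cells may therefore be maternal, so their ratios may not show an effect within cells of the fetal genotype. Different clusters held most of some classes in the 2 libraries, which values within a class carry. B cell-like cells were 884 and 272 of the wild type but 2 and 0 of the knockout in 2 clusters, against 10 and 552 in another. Endothelium-like cells were 175 and 8 in 1 cluster and 100 and 94 in another, with median UMIs of 2344 and 8678.

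**Figure D4:**
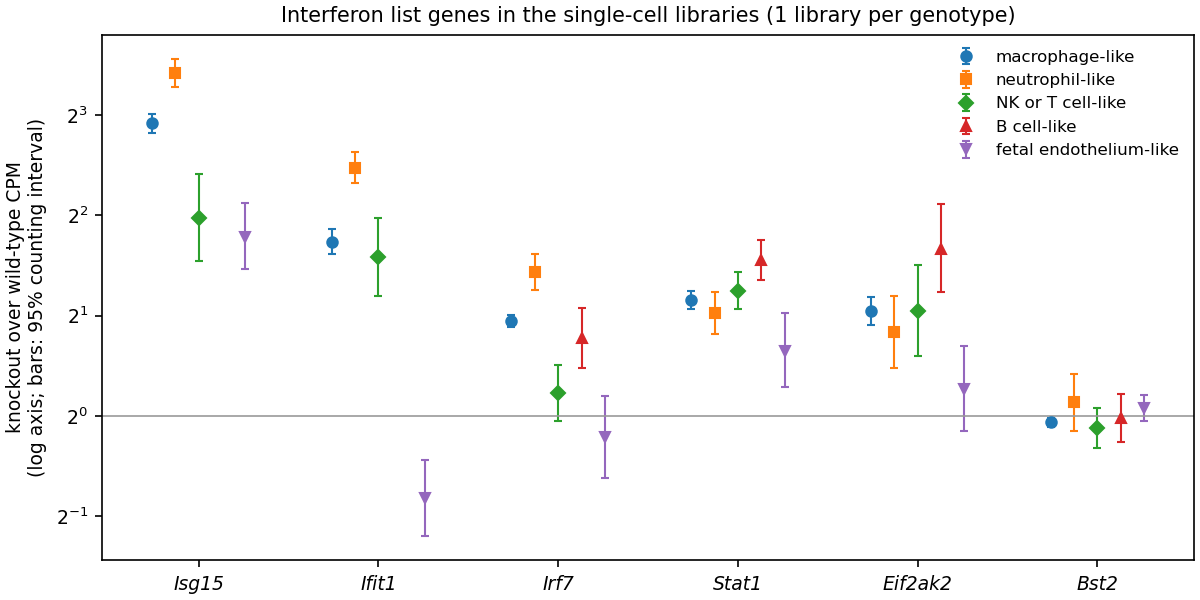
Knockout over wild-type CPM ratio (log axis) of the interferon response genes Isg15, Ifit1, Irf7, Stat1, Eif2ak2 and Bst2, where measured, in 5 classes of the single-cell libraries. Bars are 95% counting intervals, with 1 library per genotype. Isg15 lies at 10.7 in neutrophil-like and 7.55 in macrophage-like cells.

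In neutrophil-like cells inflammatory cytokine genes were also higher, 15 of 15, with a median of 1.24 above all random lists, and hypoxia genes had a median of 0.80 (15 of 16 higher). The chemokine genes Cxcl3 and Cxcl10 were 9.40 and 6.74 times higher, Gm19951 8.76 times and the receptor antagonist gene Il1rn 6.02 times. Stefin A genes, protease inhibitors of granulocytes, were far lower: Stfa3 689 times, Cstdc5 372 times, Stfa2 265 times, Stfa1 241 times and Csta2 216 times. They are near-identical copies, so that reads may be split among them. Neutrophil-like cells fell into a cluster with 491 wild-type and 319 knockout cells, a cluster led by Cxcl3 and Il1rn with 172 and 422, and a cluster led by Cstdc5 and Ngp with 93 and 1. In macrophage-like cells Cxcl3 was 10.0 times higher, Spon1 5.11 times and Gm19951 4.59 times, Stfa1 was 705 times lower (3330 and 2 counts) and Stfa3 at least 143-fold lower. Wild-type Stfa1 was at 239 CPM in macrophage-like against 15193 CPM in neutrophil-like cells, so free RNA, not tested here, may carry these 2 falls.

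In NK or T cell-like cells the chemokine gene Ccl1 was 26.5 times higher, the granzyme gene Gzmc 19.6 times, the heat shock genes Hspa1a and Hspa1b 8.25 and 7.29 times and the integrin gene Itga1 5.01 times. Il22, a cytokine gene, had 249 counts in the wild type and 0 in the knockout, at least 64.1-fold lower. In B cell-like cells Psme2b was 4.14 times, Hspa1b 3.66 times and Slc15a2 3.35 times higher. Transcripts of trophoblast stood among the lowest ratios of these classes. In B cell-like cells Prl8a9, Ceacam11, Psg23 and Psg21 were at least 119-fold, 77.4-fold, 69.9-fold and 67.2-fold lower and S100g was 134 times lower. In NK or T cell-like cells Ceacam11, Psg23, Psg16 and Psg21 were at least 55.1-fold, 51.8-fold, 50.5-fold and 47.1-fold lower, and in macrophage-like cells Psg16 was at least 65.8-fold lower and Prap1 and Psg23 242 and 230 times lower (1 knockout count each). Immune cells should lack these genes, and the wild-type library held the trophoblast cells.

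Set side by side, the directions of the 2 assays were compared gene by gene. Of the 19 genes called in the whole nuclei libraries, 18 were measured in the cells and 15 had the same sign (83.3%, Clopper-Pearson interval 58.6 to 96.4). Among autosomal calls this was 9 of 11, with Adamts13 at 148 counts in the wild-type and 5 in the knockout cells (3.34 and 0.164 CPM). The knockout library held 41 endoderm-like cells against 551 and no syncytiotrophoblast I-like or sinusoidal giant cell-like cells, and this loss alone can give a fall of genes of those cells. Of the 100 genes with the smallest p in each direction, 36 of 83 measured higher genes (43.4%) and 58 of 90 measured lower genes (64.4%) shared the sign, where 51.8% of all genes were higher in the knockout cells. This is a description across genes, which are not replicates.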

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

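The tests of Uty, of Xist in decidual stroma, of Adamts13 in cells with at least 3 Xist UMIs, of levels within the Afp-led cluster, of the other endoderm, and all 4 tests on Qpct in the library labelled wild type replicate 2 were chosen only after the result was seen, as was the limit of 20 Afp counts applied below.

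Clusters without a class enter the whole-library sums and the share denominators but have no comparison of their own. Of these, 6 stood above the wild type, either with both knockout nuclei libraries above both wild types or, in the single cells, with intervals that do not overlap. In the nuclei, cluster 26, led by Fgf14, Cadm2 and Nlgn1, held a mean of 0.33% of knockout nuclei (SD 0.114) against 0.0436% (SD 0.0106) of wild-type nuclei. Nuclei cluster 4, led by Prl5a1, had a higher knockout mean (12.8% against 2.01%) from knockout replicate 1 alone and did not meet this. Chance places both knockouts on top in 16.7% of clusters, and 4 nuclei clusters had no class. In the single cells, cluster 21, led by Serpinb9e, Serpinb9g and Serpinb9b, held 4.86% of the knockout and 0.0146% of the wild-type library (175 cells and 1 cell). Cluster 14, with Mpo, Prtn3, Acta2 and Col1a1 among its leading genes, held 6.25% against 0.567%. Cluster 7, led by Cd209a, held 7.52% against 4.06%, cluster 16, with Clec9a and Irf8, 2.80% against 1.54%, and cluster 33, with Ccl22 and Ccr7, 0.611% against 0.233%. In the other direction, with intervals that do not overlap either, cluster 1 held 0.305% of the knockout against 12.5% of the wild-type library (11 and 860 cells) and cluster 8 held 2.80% against 4.47%. With 1 single-cell library per genotype, a cluster filled mostly by 1 library can reflect that library rather than the genotype, and no explanation of these clusters was tested.

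Y-linked genes and Xist split the nuclei libraries by genotype. A change of Xist alone in pools of the same sex is argued against by Uty, at a log2 fold change of -9.35, whereas pools of different fetal sex fit the values: Xist in maternal decidual stroma-like nuclei stood at 1.16 times the wild-type level in the knockout, against 257 times in sinusoidal giant cell-like nuclei. Fetal sex as the source of the Adamts13 fall is argued against by trophoblast and endoderm cells of the wild-type single-cell library. There, cells with Xist only held 0.666 times (0.443 to 1.00) the level of cells with Y-linked UMIs only, above the bound of 0.25. With at least 3 Xist UMIs the ratio was 0.671. Most of the 51 and 51 counts came from endoderm-like cells, a class without an Adamts13 call in the nuclei. In trophoblast cells alone, a split with no bound set in advance, the ratio was 1.25 (0.504 to 3.37), on 16 and 8 counts. All of this rests on 1 library, in which free RNA, not tested there, would draw the ratio toward 1. For the other autosomal calls in sinusoidal giant cell-like nuclei, sex and genotype cannot be told apart, because the ratio of 19 higher to 10 lower genes between such wild-type cells, 1.28, has an interval (0.615 to 2.67) that spans its bound, the square root of the 4.42 between genotypes in the nuclei. The genotype itself and any strain or pool difference stay open as sources of every autosomal difference, untested.

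The Afp and apolipoprotein group, 13 genes, stood at 547 ± 138 CPM in the wild-type and 46.1 ± 24.5 CPM in the knockout nuclei libraries, and of its genes Afp, Apob and Apoa1 were called lower in 11, 10 and 9 of 12 classes and the others in 1 to 5. Less of all endoderm in the knockout pools is argued against, since the other endoderm clusters had a share 1.48 times that of the wild type (3.08% ± 0.65 against 2.07% ± 0.04). For the falls outside endoderm, free RNA of the Afp-led cluster is a candidate explanation, as the group kept the proportions of that cluster in the other classes, with a median departure of 0.226 on the log2 scale over 128 combinations of gene, class and wild-type library. Lower levels within the cluster and fewer of its nuclei cannot be told apart, because the cluster was drawn on these genes. It held 0.8787% and 0.7125% of wild-type nuclei against 0.1125% and 0.0468% of knockout nuclei (155 and 79 against 24 and 12). The level inside was 0.347 times the wild type (28003 and 92642 against 27904 and 13905 CPM). Knockout replicate 1 there lay near wild type replicate 1. Fetal sex stays open as well: in wild-type endoderm-like cells the ratio of Xist-only to Y-only cells, 0.482 (0.435 to 0.535), met the bound of 0.25 set against it, but these cells held 7 counts of Afp and so lack the cells in question, and genotype and the tissue taken into each pool were not tested.

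Qpct was near zero in the library labelled wild type replicate 2. Fewer counts are argued against, since the level of replicate 1 would give 69.9 counts where 2 were seen (upper bound 7.22), and so are fewer sinusoidal giant cell-like nuclei, where 30.3 were due and 0 seen (upper bound 3.69). For a swap with a knockout library, the highest knockout level was 0.142 CPM, below the lower bound of 1.05 CPM in replicate 1. This argues against a swap only if Qpct counts mark the genotype, which is not known here. A single wrong label cannot be told apart from a true wild type with little Qpct: Adamts13 stood at 9.89 CPM, like replicate 1, but that gene was found from the same labels. No biological explanation was tested.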

How the results depend on the processing

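The tests on autosomal genes alone, with at least 1000 genes per nucleus within classes, with parietal giant cells in place of spongiotrophoblast, without the Afp-led cluster, with named nuclei as the sum or the denominator and with TMM over the class counts were chosen only after the result was seen. Over all results and alternatives, 1323 values kept their direction and their side of the threshold, or stayed within their spread or 1.5 times their count; 216 moved, 75 lost and 20 gained their threshold, and 24 reversed. The cause of a change was not tested unless given. With 1 library left out, 1 genotype holds a lone library, which the pooled fit assumes to vary like the other group.

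Without the filter on low counts, Qpct passed its threshold at -2.60, and the calls numbered 175 in the whole libraries, 88 in decidual stroma-like, 145 in erythroid-like, 183 in endothelium-like, 60 in mesenchyme-like, 67 in glycogen trophoblast-like, 106 in macrophage-like, 132 in parietal giant cell-like, 531 in sinusoidal giant cell-like, 77 in spongiotrophoblast-like, 37 in syncytiotrophoblast I-like, 33 in syncytiotrophoblast II-like and 228 in endoderm-like nuclei, and 64 for the interaction. DESeq2 called 54 genes in the whole libraries, 23 in erythroid-like, 22 in endothelium-like, 11 in glycogen trophoblast-like, 12 in macrophage-like, 27 in parietal giant cell-like, 114 in sinusoidal giant cell-like and 18 in spongiotrophoblast-like nuclei, and its size factors in edgeR gave 1 call for the interaction. Of the 52 calls in sinusoidal giant cell-like nuclei, 50 were kept by DESeq2, 41 at the finer clustering and 27 each with doublets kept and with at least 1000 genes per nucleus. The calls there numbered 27 with doublets kept.

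Pairing the libraries by replicate number had no basis in the values: over 9387 genes the correlation of equal numbers was 0.0453. With the replicate number as a block, calls numbered 4 in the whole libraries, 0 in decidual stroma-like, 15 in mesenchyme-like, 135 in sinusoidal giant cell-like, 52 in syncytiotrophoblast I-like, 72 in syncytiotrophoblast II-like and 43 in endoderm-like nuclei. The block leaves fewer degrees of freedom.

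On autosomal genes alone, fewer genes are tested, and the calls numbered 7 in the whole libraries, 3 in decidual stroma-like, 3 in erythroid-like, 2 in endothelium-like, 1 in mesenchyme-like, 0 in glycogen trophoblast-like, 2 in macrophage-like, 7 in parietal giant cell-like, 29 in sinusoidal giant cell-like, 2 in spongiotrophoblast-like, 2 in syncytiotrophoblast I-like and 4 in syncytiotrophoblast II-like nuclei. With at least 1000 genes per nucleus there were 3 calls in decidual stroma-like, 3 in macrophage-like, 27 in sinusoidal giant cell-like and 9 in syncytiotrophoblast II-like nuclei. Without the Afp-led cluster, endoderm-like nuclei had 8 calls, as the class then lacks the nuclei that carry those genes. With parietal giant cells in place of spongiotrophoblast the interaction had 2 calls. With an estimated correlation 0 gene lists passed in the whole libraries and 0 within classes, and fry passed 1 and 1.

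Leaving out each library in turn gave, lowest to highest, Qpct at -3.52 to 1.56, 5 to 175 calls in the whole libraries, 18 to 27 in decidual stroma-like, 10 to 23 in erythroid-like, 16 to 129 in endothelium-like, 8 to 56 in mesenchyme-like, 3 to 59 in glycogen trophoblast-like, 0 to 63 in macrophage-like, 31 to 83 in parietal giant cell-like, 97 to 407 in sinusoidal giant cell-like, 12 to 132 in spongiotrophoblast-like, 23 to 53 in syncytiotrophoblast I-like, 17 to 46 in syncytiotrophoblast II-like and 28 to 177 in endoderm-like nuclei, and 0 to 1186 for the interaction. Lists that passed numbered 9 to 13 in the whole libraries and 116 to 137 within classes. Of the calls in sinusoidal giant cell-like nuclei, 41 to 51 of 52 were kept. Adjusted p ranged from 1.53e-14 to 0.0942 for the prolactin family and from 6.89e-11 to 0.228 for endoplasmic reticulum stress, both upward without knockout replicate 2 (0.0682 and 0.0829), and from 1.62e-17 to 0.243 for oxidative phosphorylation, downward without the library labelled wild type replicate 2. Share differences, in percentage points, ranged from -1.87 to 1.31 for syncytiotrophoblast I-like, -0.0770 to 0.0447 for B cell-like, -0.387 to 2.55 for erythroid-like, -2.24 to 4.71 for decidual stroma-like, -0.755 to 1.20 for glycogen trophoblast-like, -1.49 to 1.84 for endothelium-like, -0.964 to 1.16 for mesenchyme-like, -0.0593 to 0.375 for macrophage-like, -1.79 to 8.24 for sinusoidal giant cell-like and -0.142 to 0.716 for endoderm-like nuclei, so that each of these directions turned with some library left out.

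Other share differences turned as well. With doublets kept, spongiotrophoblast-like nuclei were 9.26 points higher in the knockout, because a cluster led by Prl5a1, Prl8a2 and Doxl1 then takes that name, and syncytiotrophoblast I-like nuclei 0.358 points higher. Syncytiotrophoblast I-like nuclei were also 1.80 points higher among trophoblast nuclei and 0.246 among named nuclei, B cell-like nuclei 0.00812 points higher among named nuclei, and mesenchyme-like nuclei -0.00446 with TMM over the class counts. In the single cells, with at least 1000 genes per cell, the ratio of shares was 29.0 for megakaryocyte or platelet-like, 1.20 for neutrophil-like, 13.3 for parietal giant cell-like and 0 for spongiotrophoblast-like cells, where fewer cells remain. At the finer clustering it was 1.39 for neutrophil-like and 0.251 for parietal giant cell-like cells, which reversed because cells of that class were then named junctional zone progenitor. No value could be given for parietal giant cell-like cells with doublets kept, where no cluster took that name, or for erythroid-like cells with at least 1000 genes per cell, where none remained. Among named genes of the single cells, Ldoc1, Prap1 and Guca2b moved with all deposited barcodes, to ratios of 77.0, 0.0169 and 0.00690, and Prl8a6 to 0 with at least 1000 genes per cell.

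Not every change can be called with 2 against 2. In simulated counts of the whole libraries' size, 57% of 2-fold and 99% of 4-fold changes were called, among genes above a minimum mean count. Depth and sample number were not varied.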

Other observations

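The genes and classes given here were chosen only after the result was seen, and no tests were run on them beyond the lists.

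Endothelium-like cells of the knockout single-cell library carried the transcripts of dividing cells. All 14 S phase and 21 G2 and M phase genes measured were higher, with median log2 ratios of 3.79 and 4.12, above all 10000 random lists. Mki67 was 20.7 times higher (interval 11.1 to 43.6; 10 and 262 counts) and Top2a, a topoisomerase of dividing cells, 36.7 times. All 29 oxidative phosphorylation genes were higher (0.90), while immediate early and heat shock genes lay below all random lists (-1.12; 2 of 22 higher). The 2 libraries filled different endothelial clusters, so this compares unlike sets of cells. In endothelium-like nuclei the S phase and G2 and M phase medians were 0.01 and 0.07 (camera adjusted p = 0.899 and 0.901, n = 2 and 2).

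Myeloid cells of the knockout library differed in several gene sets. In neutrophil-like cells Ccl3, a chemokine gene, was 5.09 times and Tnf 2.46 times higher, the interferon response genes Rsad2 and Ifit1 were 5.46 and 5.56 times higher, and 10 of 10 mitochondrially encoded genes were higher (median 0.94). In macrophage-like cells 19 of 19 hypoxia genes were higher (median 0.42, percentile 98.1), as were 11 of 13 genes of glycogen metabolism (0.53, percentile 99.4) and 10 of 11 of cholesterol and steroid synthesis (0.54, percentile 99.1). Bst2, an interferon-induced surface protein gene, stayed near 1 in all 5 classes measured, from 0.920 times in NK or T cell-like to 1.10 times in neutrophil-like cells. In endothelium-like cells Isg15 was 3.45 times higher and Rsad2 0.470 times the wild type. Il1b was lower in B cell-like (0.247 times), NK or T cell-like (0.310 times), endothelium-like (0.175 times) and macrophage-like cells (0.760 times), and 1.22 times the wild type in neutrophil-like cells, where its level was highest.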
